A study of Mus musculus with 9 samples.

How the data were processed

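Skin of C57BL/6J mice aged 8 weeks was treated for 7 days with 5% imiquimod cream, with or without traction, and its total RNA was isolated, per the labels' protocols. Biotinylated cRNA was made from 6 ug of total RNA by the manufacturer's standard protocol, per the labels' protocols. The deposited table held log2 expression values for 22206 features (transcript clusters) on 9 arrays. RMA and Transcriptome Analysis Console are the tools named for these deposited log2 values, per the submitters' processing notes, which give no versions. RMA commonly corrects background, quantile-normalizes probes and summarizes them per feature on the log2 scale, which compresses low values towards a floor, so that fold changes of low genes are understated. The genome build, the annotation version and any filter are not given in the sources used here, and coordinates are not printed. Scanner intensities and detection calls were not used here, so whether a feature lay above background was not assessed, and levels are described only by their rank among all genes.

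Samples were grouped by their titles into stretch (n = 5) and no stretch (n = 4), and all 9 columns were matched to samples by their identifiers. No 2 arrays held identical values. Gene names came from the platform annotation table: 19572 features had 1 gene symbol, none had several, and 2634 were unnamed here. Symbols were looked up again through Entrez identifiers in a mouse RefSeq table of GRCm38.p6, which changed none of them. Where several features named a gene (55 genes), the one with the highest mean over all 9 arrays was used, giving 19505 genes. Some list members, such as Krt6a, were not found under their name: 627 of 686 list entries were measured. Among the genes, 39 shared identical values on all arrays with another gene, and the array does not separate these.

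Differences were computed as stretch minus no stretch with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with no covariate, and adjusted by Benjamini-Hochberg over all genes with a threshold of 0.05. Fold changes are 2 to the power of the log2 change. Standard errors and 95% confidence intervals come from the moderated fit. Il1b and Il6 were also tested by an exact permutation of the difference in means over all 126 splits of the arrays into 5 and 4, whose smallest possible p is 0.0079. Gene lists (36, each with at least 5 measured members) were tested with camera at a preset correlation of 0.01, adjusted over the lists; camera asks whether a list's genes moved more than other genes. Estimated correlations, camera on ranks, fry and a permutation of per-array list means were alternatives. Several lists share members, such as Il1b, Csf3 and Krt79. The comparison, the lists, the tests, the alternatives other than the omission of 2 arrays, and the rule for named genes were fixed before the data were examined.

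The named genes were the 10 of largest rise and the 10 of largest fall among those past the threshold (predicted genes without a proper symbol passed over), the preset genes Il1b, Il6, Il17a, Il17f, Il22, Il23a, Tnf, Cxcl1, S100a8 and Krt6a, and up to 4 members of each list with the smallest p. Genes outside this rule are Nid1, Cxcl15 and Tnc in the report and, in the closing section, Smpx, Tnxb, Islr, Ccl21a and members of lists written later; they were chosen after their values were seen. Alternatives covered renormalization, filters on dim genes, averaging of features, the variance model, array weights, the replicate number as a block, other thresholds, all features, and leaving out each array. On data simulated from the means and spreads of these 19505 genes, with 200 genes changed, the gene test recovered 39% of 2-fold, 92.5% of 4-fold and 98.5% of 8-fold changes, and between 3.70% and 5.61% of its calls were false; the simulation draws genes independently. An adipocyte list shifted by 1 on the log2 scale was recovered and no other list was called there.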

Results

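Gene expression was measured with biotin-labelled cRNA on Affymetrix arrays in back skin of C57BL/6J mice that all received imiquimod cream, a Toll-like receptor agonist used to induce psoriasis-like dermatitis in mice. In 5 samples the skin had also been held under traction with a glued plastic device elongated by 10 mm, and in 4 samples it had not. The protocol text is the same for all samples and does not say whether the non-stretched skin also carried the glued device, so differences described here as with stretch can include effects of the device itself. The comparison addresses which genes and pathways differ when the inflamed skin is mechanically stretched. The labels do not say that each sample came from a separate mouse, so the p-values measure the spread between these samples, which may in part be technical. The arrays gave log2 expression values for 22206 features, of which 19572 carried a gene name and represented 19505 genes. The number of arrays limits the precision: the median standard error of a log2 change was 0.21. Array medians lay between 5.81 and 5.99 on the log2 scale. The array of no-stretch replicate 3 had the lowest median correlation with the other arrays (r = 0.9749, against 0.980 to 0.987 for the other 8, across genes), and it and stretch replicate 1 received the lowest array weights (0.58 and 0.55). No array without imiquimod was analysed here, so changes caused by imiquimod itself cannot be read from these data.

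**Figure D1:**
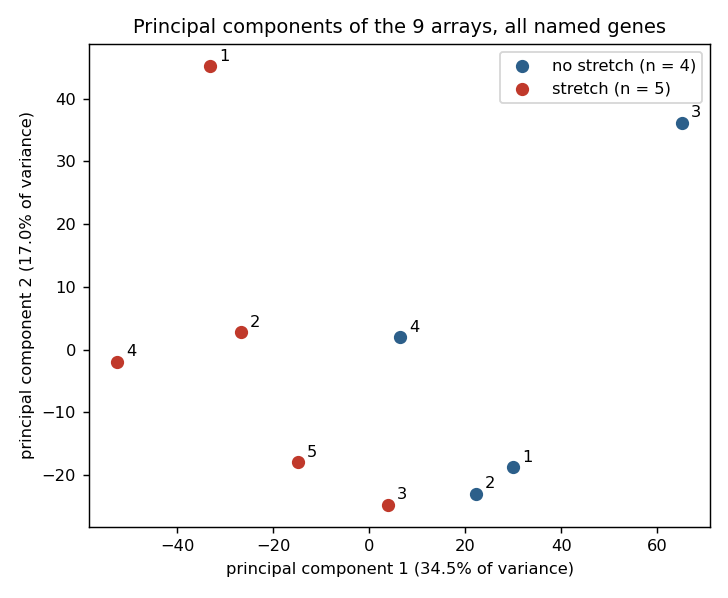
Principal components 1 and 2 of the 9 arrays, computed on the log2 values of all 19505 named genes; each point is an array, numbered by replicate and coloured by group. The components hold 34.5% and 17.0% of the variance, and no-stretch replicate 3 lies farthest to the right, at 65.2 on component 1.

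Stretched skin differed from non-stretched skin at 48 genes, of which 16 rose and 32 fell. Among the genes past the threshold, those that rose most were Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, which was 12.2-fold higher, and Ankrd2, a stretch-responsive ankyrin-repeat protein of muscle, which was 11-fold higher. Upp1, a uridine phosphorylase, and Mrgpra2b, a Mas-related receptor, were each 9.78-fold higher. Sln (sarcolipin, a regulator of the muscle calcium pump), Mybph and Csrp3, both proteins of the muscle sarcomere, rose 6.69-fold, 5.06-fold and 4.66-fold. Defb14, a beta-defensin, rose 5.17-fold, the collagenase gene Mmp13 4.77-fold and the tetraspanin gene Tspan4 4.41-fold. Among the genes that fell, Retnla, a marker of alternatively activated macrophages, was 15.1-fold lower. Arg1, from the same list of type 2 genes, went the other way without passing (6.61-fold higher, limma adjusted p = 0.095). Without no-stretch replicate 3 the log2 change of Ptgs2 went from 3.61 to 2.97 and that of Retnla from -3.92 to -3.17, and neither passed (limma adjusted p = 0.10 and 0.083). Thrsp, a lipogenic gene, was 6.07-fold lower, and Fasn, the fatty acid synthase, 4.76-fold lower. Dpt, the matrix protein dermatopontin of fibroblasts, was 4.94-fold lower, Igfbp5 was 4.55-fold lower and Itih5 4.36-fold lower. Lhx2, a transcription factor of hair follicle stem cells, was 4.85-fold lower, and Dct, an enzyme of melanin synthesis, 4.76-fold lower. The smallest p-value belonged to Cd34, a surface antigen of hair follicle stem cells, dermal fibroblasts and vessels. It was 12.20 ± 0.10 (SD, n = 5) with stretch and 13.81 ± 0.18 (SD, n = 4) without, a log2 change of -1.604 with a standard error of 0.15 and limma adjusted p = 0.0046. Ccl21b and Ccl21c, chemokines of lymphatic endothelium, were listed with identical values on all arrays, which were 4.16-fold lower with stretch; the array does not separate these near-identical copies, and they count as 2 of the 48 genes.

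The test was limma's moderated test with Benjamini-Hochberg adjustment over 19505 genes at 0.05, and the 20 genes of largest change had adjusted p-values between 0.021 and 0.048. The 2 groups did not overlap on any array for 48 of the 48 genes; among all genes 885 did not overlap (4.54%, where chance gives 1.59%). Without correction, 2533 genes had p under 0.05, where 975 would be expected by chance, and 93 higher and 118 lower genes passed an adjusted p of 0.1. Which genes were called depended on single arrays: 195 genes passed without stretch replicate 3, 75 without no-stretch replicate 4, 71 without stretch replicate 1, 22 without stretch replicate 4, 13 without stretch replicate 5, 8 without no-stretch replicate 2, 6 without no-stretch replicate 1, and 2 each without stretch replicate 2 or no-stretch replicate 3. Cd34 and Nid1, a basement membrane gene chosen here after its values were seen, passed in all 9 of these fits. The direction of all 48 genes was the same in each of the 9, but leaving out an array could not turn it, since their groups do not overlap.

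Il1b and Il6, the cytokine genes named in the title of the series, were higher in all 5 stretched samples than in all 4 non-stretched ones. Il1b was at 13.72 ± 1.57 (SD, n = 5) with stretch and 10.00 ± 1.25 (SD, n = 4) without, which is 13.1-fold higher (log2 change 3.71, 95% confidence interval 2.04 to 5.38). Il6 was at 10.70 ± 1.72 (SD, n = 5) against 6.51 ± 1.58 (SD, n = 4), which is 18.2-fold higher (log2 change 4.19, 95% confidence interval 2.27 to 6.11). Each difference had an exact permutation p of 0.016 (two-sided over 126 splits, and the same after Benjamini-Hochberg over both genes), while limma's adjusted p over all genes was 0.070 for Il1b and 0.076 for Il6, which missed the threshold. Leaving out single arrays moved the log2 change between 3.26 and 4.22 for Il1b and between 3.60 and 4.86 for Il6. The adjusted p over all genes ranged from 0.023 to 0.240 for Il1b and from 0.034 to 0.241 for Il6 across these fits. It was 0.023 for Il1b and 0.034 for Il6 without stretch replicate 3, and 0.046 for Il6 without no-stretch replicate 4.

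The genes of the IL-23/IL-17 axis, the T-cell pathway that imiquimod dermatitis is known to engage, did not differ as a group. None of the 17 measured members passed the test, over all genes or adjusted over the list alone. Their mean log2 change was -0.002, a value that turned positive under quantile normalization (0.025) and median centring (0.067), and the list had camera adjusted p = 0.50. Il17a had a log2 change of 0.12 (95% confidence interval -0.30 to 0.55), Il17f 0.34 (-0.37 to 1.05), Il22 0.21 (-0.26 to 0.68) and Il23a -0.04 (-0.51 to 0.43), the last again positive under both scalings (0.015 and 0.027). Il17f was at 5.27 in stretch replicate 3 but at 3.53 to 3.85 in the other stretched arrays, near the non-stretched mean of 3.67, so that array carries its change. The levels of these 4 genes lay low among all genes, at percentiles 34.4, 25.1, 12.2 and 10.1. Detection calls are not among the values used here, so an undetected difference in these genes is not evidence of a constant level. Tnf changed by 0.53 (-0.54 to 1.60). Among the other members of the axis, Il24 had a log2 change of 1.86 and Il23r of -0.65, with limma adjusted p = 0.19 and 0.24.

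**Figure D2:**
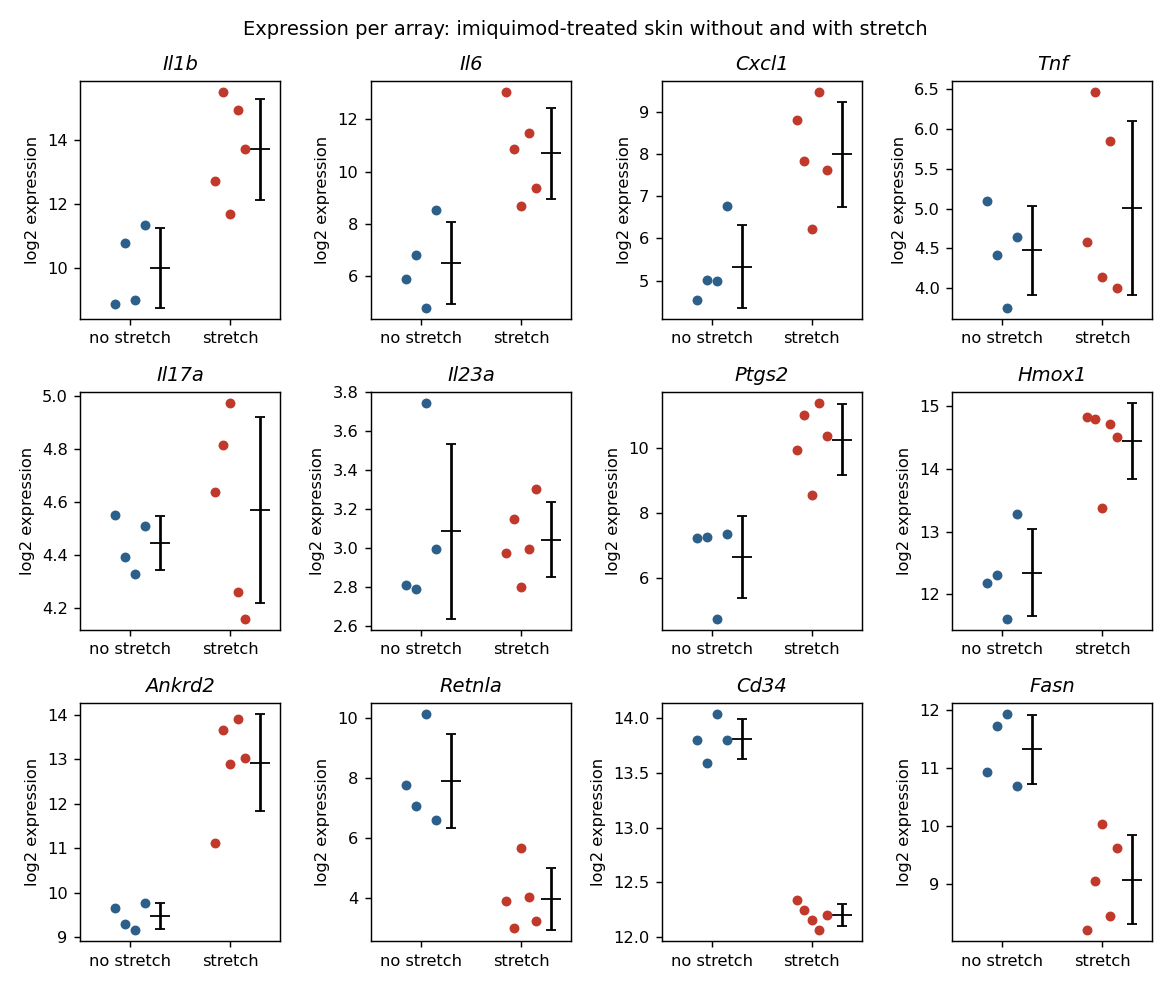
Log2 expression of 12 genes on each array (points; blue, no stretch, n = 4; red, stretch, n = 5) with the mean and SD of each group in black. Il1b, Il6, Ptgs2, Hmox1 and Ankrd2 lie higher in every stretched sample and Retnla, Cd34 and Fasn lower, whereas Cxcl1, Tnf, Il17a and Il23a overlap. The vertical axes do not start at 0 and differ between panels.

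Gene lists fixed in advance were tested with limma's camera, and 23 of 36 passed, 14 higher and 9 lower with stretch. These calls rest on a preset correlation between genes of 0.01. With the correlation estimated from the arrays 0 lists passed at an adjusted p of 0.05, the smallest being 0.080, and 11 had an unadjusted p under 0.05. Limma's fry called 13 lists and an exact permutation of list means 0. Other splits of the same 9 arrays called a median of 10 lists. No-stretch replicate 3, which stood apart from the other arrays, also had the lowest mean of all 9 arrays for 13 of the 14 higher lists, the exception being immediate early genes. On single arrays the list means of the 2 groups overlapped in 12 of the 23 lists. Means of no-stretch replicate 3 lay between -0.77 (neutrophil chemokines) and -0.19 (IL-1 family) relative to the non-stretched mean in the 13. Of the 23 lists, 21 passed in all 9 fits that left out 1 array, and 23 lists passed without no-stretch replicate 3 and stretch replicate 1 together, 22 of them among the original 23. The same omission, chosen after seeing the data, left 15 genes past the threshold, 9 of them among the 48.

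The largest shift was in neutrophil chemokines and their inducers. Their mean log2 change was 2.58, and 9 of the 10 members were higher. Cxcl2 and Cxcl5, ligands of the neutrophil receptor CXCR2, were 44.4-fold and 19.6-fold higher, and Cxcl1 was 6.33-fold higher. None of the 10 passed over all genes (limma adjusted p = 0.054 for Cxcl2, 0.077 for Cxcl5 and 0.094 for Cxcl1), but adjusted over the list alone 9 were higher and 1, Cxcl15, lower (log2 change -0.52). Leaving out single arrays moved the log2 change between 4.81 and 6.24 for Cxcl2 (5.47 with all arrays) and between 3.63 and 5.34 for Cxcl5 (4.29), the lowest values being without no-stretch replicate 3. Both genes passed over all genes without stretch replicate 3 and without no-stretch replicate 4. Cxcl5 overlapped between the groups, at 10.26 in stretch replicate 3 and 10.95 in no-stretch replicate 4. So did Cxcl1, at 6.22 and 6.76 in the same arrays. The list had camera adjusted p = 2.4e-09, and adjusted p = 0.15 with an estimated correlation. The level in the lowest stretched sample, replicate 3 (1.22 above the non-stretched mean), was close to that in the highest non-stretched one, replicate 4 (1.15).

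Neutrophil markers shifted the same way, with a mean log2 change of 1.36 and 19 of 21 members higher. Clec4e, a C-type lectin receptor of myeloid cells, was 9.07-fold higher, Stfa2l1, a stefin of neutrophils, 3.50-fold higher and the gelatinase gene Mmp9 3.34-fold higher. None passed over all genes and 11 were higher when adjusted over the list alone (camera adjusted p = 1.0e-08, and adjusted p = 0.14 with an estimated correlation). S100a8, which neutrophils and activated keratinocytes both express at high level, was at 18.09 ± 0.90 (SD, n = 5) against 17.50 ± 0.75 (SD, n = 4), a log2 change of 0.59 (95% confidence interval -0.41 to 1.58). Monocyte and macrophage markers had a mean log2 change of 0.63, with 16 of 18 members higher, none past the threshold over all genes and 1, Cd14, adjusted over the list alone. Cd14, the lipopolysaccharide co-receptor, was 4.78-fold higher, the scavenger receptor Msr1 3.15-fold and Cd163 1.80-fold. This list had camera adjusted p = 0.00016, and adjusted p = 0.30 with an estimated correlation, and its mean change was 0.36 without the 2 arrays of lowest weight. The groups overlapped: the list mean was -0.01 in stretch replicate 3, and 0.64 and 0.04 in no-stretch replicates 4 and 2.

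Cytokine pathway lists were also higher. The IL-6 family and STAT3 list had a mean log2 change of 0.80, with 14 of 18 members higher and 8 past the threshold when adjusted over the list alone. Timp1, a metalloproteinase inhibitor induced by these cytokines, was 6.44-fold higher and Osm, oncostatin M, 3.51-fold. The list had camera adjusted p = 4.2e-05, and adjusted p = 0.21 with an estimated correlation. The IL-1 family and inflammasome list had a mean log2 change of 0.60 and 4 of its 19 members, all higher, passed adjusted over the list alone. Besides Il1b, these were Nlrp3, an inflammasome sensor, at 7.13-fold, the alarmin Il33 at 3.37-fold, and the decoy receptor Il1r2. Camera adjusted p was 0.00082, and adjusted p = 0.15 with an estimated correlation. In the TNF and NF-kB list Ptgs2 passed over all genes, 5 of 19 members passed adjusted over the list alone, and the mean log2 change was 0.61; Csf3, the neutrophil growth factor G-CSF, was 2.0-fold higher and the adhesion molecule Icam1 1.5-fold. Its camera adjusted p was 0.00012, and adjusted p = 0.15 with an estimated correlation. Type II interferon and Th1 genes had a mean log2 change of 0.59 with no member past either threshold; Nos2 was 3.43-fold, Ifng 2.04-fold and Cd274 2.57-fold higher (camera adjusted p = 0.0018, and adjusted p = 0.27 with an estimated correlation). Without no-stretch replicate 3, which lay at -0.73, the mean change of the type II interferon list was 0.35 (adjusted p = 0.025). Il1b and Il6, which the series title names, belong to these lists, so the lists are not fully independent of the study's own finding.

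Lymphocyte and antigen-presenting cell lists went the other way or did not differ. Dendritic and Langerhans cell markers were lower, with a mean log2 change of -0.29 and 13 of 19 members negative, none past either threshold. The MHC class II genes H2-Aa and H2-Eb1 were 2.09-fold and 2.04-fold lower, and Xcr1, a receptor of cross-presenting dendritic cells, 1.46-fold lower (camera adjusted p = 0.012, and adjusted p = 0.15 with an estimated correlation). T cell markers had a mean log2 change of -0.27, with 12 of 13 members negative; Cd4 was 1.87-fold lower, Icos 1.68-fold and Zap70 1.24-fold. Their camera adjusted p was 0.030, and adjusted p = 0.31 with an estimated correlation, and the call was lost without stretch replicate 2, 4 or 5 or no-stretch replicate 2 (adjusted p up to 0.22), and after quantile normalization. Without no-stretch replicate 2 the mean change was -0.18. No T cell member passed either threshold. B and plasma cell, mast cell and Th2 lists did not pass (camera adjusted p = 0.29, 0.097 and 0.46). Among camera's fits that left out 1 array, the mast cell list passed only without stretch replicate 4, whereas fry called it on all arrays (fry adjusted p = 0.021). Within these lists, Blk was lower and 4 Th2 members, among them Arg1 (6.61-fold), were higher, adjusted over the list alone, whereas Retnla fell over all genes. The mast cell carboxypeptidase gene Cpa3 was 2.55-fold lower (log2 change -1.35, limma adjusted p = 0.084 over all genes), past the threshold adjusted over the list alone. The type I interferon list, which imiquimod is known to induce, had a mean log2 change of 0.06 and camera adjusted p = 0.87. Its list mean varied widely within both groups, from -0.75 to 1.701 relative to the non-stretched mean with stretch and from -1.42 to 1.37 without. Its mean change turned to -0.41 without no-stretch replicate 3 and passed (adjusted p = 0.017), and to 0.52 without no-stretch replicate 2, where it also passed (adjusted p = 0.013).

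In the epidermis, the list of activated keratinocyte genes was higher with stretch and that of terminal differentiation lower, with overlap between the groups on single arrays. Activated keratinocyte genes had a mean log2 change of 0.70, with 18 of 25 members higher and 6 past the threshold adjusted over the list alone. The late cornified envelope gene Lce3d was 4.98-fold, the cornified envelope precursor Sprr1a 4.05-fold and the growth factor Hbegf 3.36-fold higher. This list had camera adjusted p = 8.0e-05, and adjusted p = 0.31 with an estimated correlation. Its mean was -0.0044 in stretch replicate 4 and 0.85 in no-stretch replicate 2, relative to the non-stretched mean, and its change was 0.45 without stretch replicate 3. Terminal differentiation genes had a mean log2 change of -0.70, with 29 of 31 members lower and none past either threshold. Flg2, a filaggrin-like barrier protein, was 3.34-fold lower, the lipoxygenase gene Aloxe3 2.68-fold and Lor, loricrin, 1.98-fold (camera adjusted p = 3.3e-08, and adjusted p = 0.31 with an estimated correlation). Its mean was 0.07 in stretch replicate 5 and -0.29 in no-stretch replicate 2, and its change was -0.46 without stretch replicate 4. Basal keratinocyte markers had a mean log2 change of 0.33, with 9 of 12 higher. Lama3, a laminin chain of the basement membrane, was 2.33-fold higher and passed adjusted over the list alone, Lamb3 was 2.07-fold and Sfn 1.62-fold higher (camera adjusted p = 0.0041, and adjusted p = 0.29 with an estimated correlation). The change of the basal list was 0.21 without no-stretch replicate 3. Cell cycle genes had a mean log2 change of 0.34, with 20 of 23 positive and none past either threshold. Cdk1 was 2.28-fold, Birc5 1.94-fold and Bub1 1.74-fold higher. Their camera adjusted p was 0.00018, adjusted p = 0.34 with an estimated correlation, and 0.0505 without the 2 arrays of lowest weight, which ended the call. Antimicrobial peptide genes did not pass as a list (camera adjusted p = 0.094) and passed without stretch replicate 4 or no-stretch replicate 2. Defb14 rose over all genes, and Saa3, an acute-phase protein, was 3.25-fold higher, adjusted over the list alone. Krt6a was not measured under that name here.

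Lists of skin appendages, fat and pigment cells were 5 of the 9 lower lists. The sebaceous gland and lipid synthesis list had the largest mean log2 change among them, -1.31, with 19 of 20 members lower, 1 past the threshold over all genes and 11 adjusted over the list alone. Besides Fasn, the desaturase gene Scd3 was 6.79-fold and the upper-follicle and sebaceous duct keratin Krt79 5.42-fold lower (camera adjusted p = 6.2e-11, and adjusted p = 0.15 with an estimated correlation). The groups overlapped: the list mean was -0.72 in no-stretch replicate 4 and -0.49 in stretch replicate 3. Adipocyte markers had a mean log2 change of -0.95, with 12 of 13 lower, Thrsp past the threshold over all genes and 9 adjusted over the list alone. Adipoq, the adipokine adiponectin, was 3.36-fold and the lipid droplet protein gene Plin1 2.85-fold lower (camera adjusted p = 3.3e-08, and adjusted p = 0.15 with an estimated correlation). Hair follicle stem cell markers had a mean log2 change of -0.76, with 11 of 13 lower, Cd34 and Lhx2 past the threshold over all genes and 6 adjusted over the list alone (camera adjusted p = 6.3e-06, and adjusted p = 0.080 with an estimated correlation). Their median change was smaller, -0.43. Krt79 also counts in the sebaceous list, and Cd34 is also an antigen of dermal fibroblasts and vessels, so this list is not specific to stem cells. Hair shaft and inner root sheath genes had a mean log2 change of -0.42. Krt73, a keratin of the inner root sheath, fell 3.88-fold over all genes, and Krt28 and Krt25 were 4.03-fold and 3.47-fold lower, adjusted over the list alone, where 4 of 27 passed. Krt28 and Krt25 were at 3.93 and 3.32 with stretch, and at percentiles 38.0 and 29.1 of all genes. This list had camera adjusted p = 0.00046, and adjusted p = 0.25 with an estimated correlation. Melanocyte markers had a mean log2 change of -0.54, with 10 of 12 lower, Dct and Pmel past the threshold over all genes and 5 adjusted over the list alone. Pmel, a melanosome protein, was 2.64-fold and the melanin synthesis gene Tyrp1 2.46-fold lower (camera adjusted p = 4.2e-05, and adjusted p = 0.080 with an estimated correlation).

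Matrix genes split by class. Matrix proteases and the plasminogen system had a mean log2 change of 1.16, with 15 of 19 members positive, Mmp13 past the threshold over all genes and 12 higher adjusted over the list alone. The collagenase gene Mmp1b was 5.96-fold higher. This list had camera adjusted p = 3.3e-08, and adjusted p = 0.15 with an estimated correlation. Fibroblast and extracellular matrix genes had a mean log2 change of -0.39, with 15 of 18 negative. Fn1, fibronectin, fell 3.55-fold over all genes. Adjusted over the list alone 6 were lower, among them the elastin gene Eln (2.05-fold) and Col1a2 (1.77-fold), and 1, the tenascin gene Tnc, was higher (log2 change 2.11). The list had camera adjusted p = 3.0e-05, and adjusted p = 0.25 with an estimated correlation. Myofibroblast and TGF-beta response genes did not pass as a list (camera adjusted p = 0.26), with Inhba 2.44-fold and Smad7 1.64-fold higher, adjusted over the list alone.

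The lists closest to mechanical sensing did not pass. YAP/TAZ target genes, a readout of mechanotransduction in many cell types, had a mean log2 change of 0.22 and camera adjusted p = 0.44. Adjusted over the list alone 3 of 23 were higher and 2 lower. Ankrd1, a cardiac and muscle ankyrin-repeat protein, was 9.33-fold higher (limma adjusted p = 0.054 over all genes) and Gadd45b 2.31-fold. The 2 lower ones were Axl (1.87-fold) and Ptpn14 (1.82-fold). Mechanosensors and focal adhesion genes had a mean log2 change of 0.14 and camera adjusted p = 0.11, with the integrin genes Itga5 and Itga2 1.94-fold and 1.59-fold higher and none of 21 past either threshold. Its mean change ranged from 0.04 without no-stretch replicate 3 to 0.20 without stretch replicate 3, and of the 9 fits that left out 1 array only the latter passed. Skeletal muscle markers did not pass (mean log2 change -0.02, turning to 0.05 under median centring, camera adjusted p = 0.84), and camera's direction was higher, opposite to the mean. Their list mean was lowest in stretch replicate 1, which lay at -1.35 relative to the non-stretched mean. Without that array the mean change was 0.31 and passed (adjusted p = 0.0034). Xirp2 and Actn3 were 2.24-fold and 1.99-fold higher without passing either threshold.

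Stress and metabolic lists were higher. The oxidative stress list had a mean log2 change of 0.66, with 12 of 14 members positive. Hmox1, heme oxygenase 1, rose 4.27-fold over all genes. Gsta4, a glutathione transferase, was 5.92-fold higher and catalase, Cat, 2.07-fold lower, both adjusted over the list alone (camera adjusted p = 0.00013, and adjusted p = 0.14 with an estimated correlation). Hypoxia and glycolysis genes had a mean log2 change of 0.58, with 18 of 19 positive and 10 past the threshold adjusted over the list alone. The glucose transporter gene Slc2a1 was 1.93-fold, Bnip3 1.90-fold and Ero1a 1.81-fold higher (camera adjusted p = 9.2e-08, and adjusted p = 0.15 with an estimated correlation). Immediate early genes had a mean log2 change of 0.42. Ier3 was 3.77-fold higher, adjusted over the list alone, and Junb 2.34-fold higher while Egr3 was 2.0-fold lower. Their camera adjusted p was 0.037, adjusted p = 0.59 with an estimated correlation, and the call was lost without stretch replicate 3, 4 or 5 or no-stretch replicate 2 (adjusted p up to 0.43), and after quantile normalization or median centring. The mean change was 0.66 without stretch replicate 1, 0.17 without stretch replicate 5 and 0.20 without no-stretch replicate 2. Endothelial, Schwann cell, and erythrocyte and platelet lists did not pass (camera adjusted p = 0.42, 0.53 and 0.43), and the Schwann cell list had a mean log2 change of -0.08 but a median of 0.0085. Tek, an angiopoietin receptor, was 1.79-fold lower, adjusted over the endothelial list alone.

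**Figure D3:**
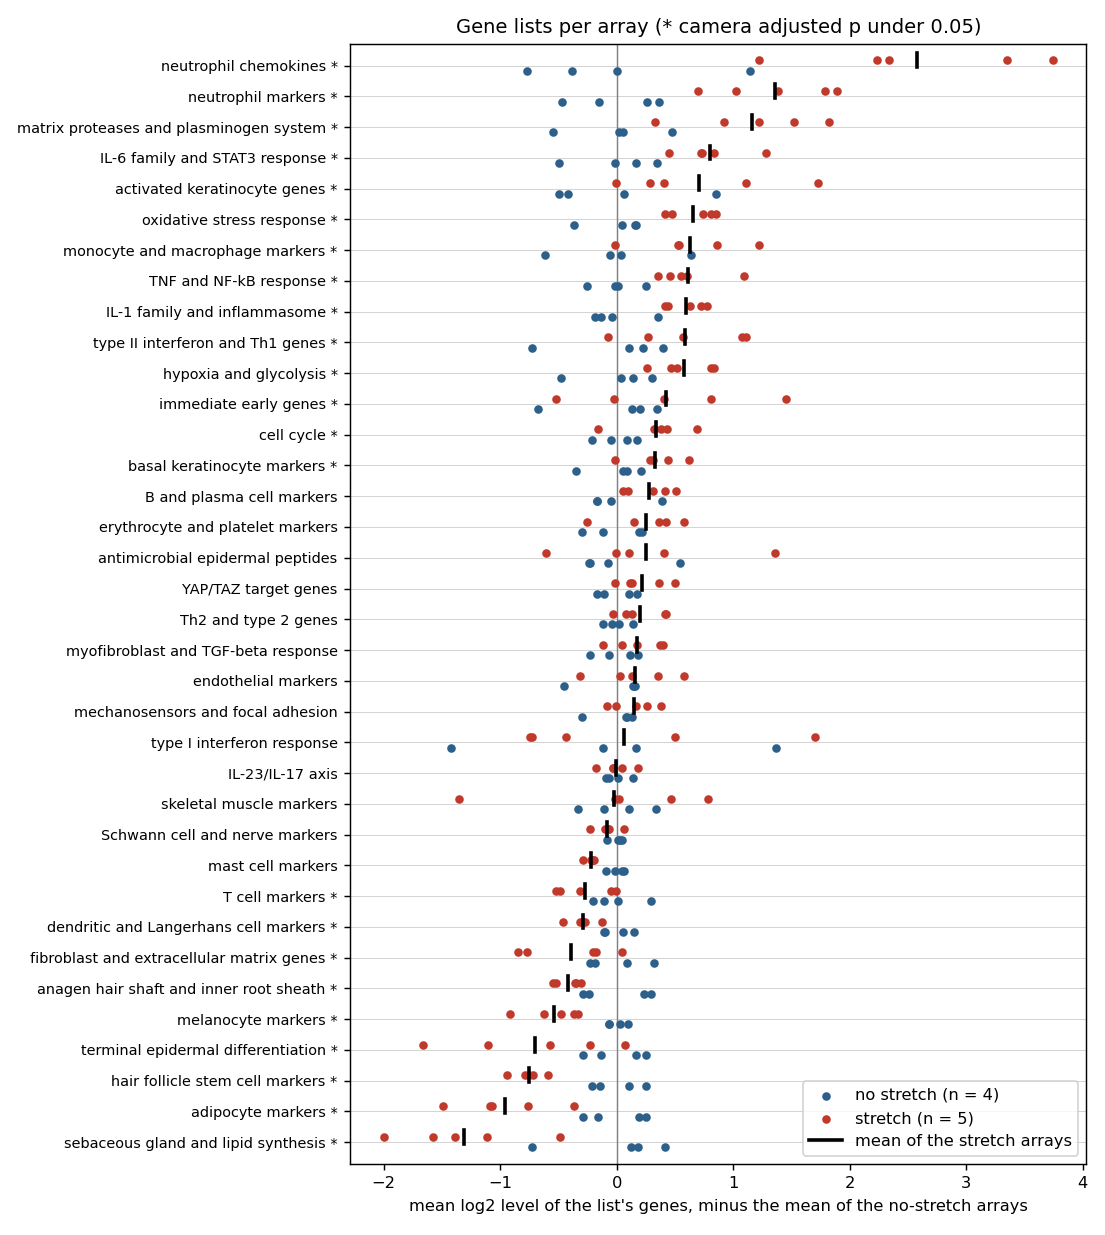
Mean log2 level of each gene list on each array, relative to the mean of the non-stretched arrays (blue, no stretch, n = 4; red, stretch, n = 5; black bars, mean of the stretched arrays), with an asterisk for lists past camera's adjusted threshold. Neutrophil chemokines lie farthest right, with a mean of 2.58, and the sebaceous gland and lipid synthesis list farthest left, with -1.31.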

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

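The tests of dilution, of tissue depth, of leukocytes in general and of muscle content were chosen after the list values had been seen; the tests of array quality, array scale and sample splits were set out before their results. In 298 groups of values the most extreme sample was compared with the others by Dixon's ratio at the 95% level; 18 groups stood out, where chance gives about 15, and 6 of them were in no-stretch replicate 3.

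In no-stretch replicate 3, Ptgs2 (4.75, the others 7.23 to 7.37), Rsad2 (5.43), Bnip3 (9.59) and Slc2a1 (14.19) lay far below the other 3 arrays of the group, as did the mean of the mechanosensor list (8.10) and of the endothelial list (7.11). In no-stretch replicate 4, Cdk1 (7.81), Col1a2 (16.11) and Gadd45b (7.43) lay above the others. In stretch replicate 1, the muscle genes Mybph (9.49), Csrp3 (11.94) and Actn3 (10.39) and the endothelial receptor gene Tek (6.28) lay below the others. In stretch replicate 3, Il17f (5.27) lay above the others and Il24 (6.20) and Hmox1 (13.37) below. H2-Aa was low in stretch replicate 4 (11.53), and the mast cell list in stretch replicate 2 (5.55). Of the features with no gene name, which the gene test did not use, 9 passed the threshold when all features were tested, 4 higher and 5 lower, against 5.38 at the rate of the named genes.

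The first pattern is the lower level of the hair follicle stem cell, sebaceous, adipocyte and melanocyte lists. Equal dilution of all resident cells as the whole cause would lower other resident lists by as much. The 7 other resident cell lists fixed in advance had a joint mean change of -0.16. They include the lower lists of terminal differentiation (-0.70, further than melanocytes at -0.54), hair shaft (-0.42) and fibroblasts (-0.39). The endothelial, basal keratinocyte and Schwann cell lists alone had 0.13. The 4 lists lay below both sets (differences of -0.73 and -1.02, exact permutation p = 0.0079 for each, two-sided, the smallest that 126 splits can give). The 4 lists were picked for their fall in these arrays, so these p-values are not evidence by themselves. The unequal changes of the 7 lists, from -0.70 to 0.33 (basal keratinocytes), go against equal dilution as the whole cause, but their inequality was not tested. The 2 arrays of lowest weight are also argued against, since 4 of the 4 lists kept their camera call and at least 0.954 of their change without them. Less deep tissue in the stretched samples cannot be told apart from a change in these cells, because the muscle list was too variable: the adipocyte list lay 0.93 below it (difference -0.93, exact permutation p = 0.11). A loss or a changed state of these cells under stretch stays open and was not tested.

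The second pattern is the higher level of neutrophil markers and chemokines. A difference in array scale left in the deposited values is argued against, since the mean change of the members was 1.76 after quantile normalization and 1.75 as deposited. RMA commonly quantile-normalizes already, so repeating it could change little and does not test scale before RMA. An equal increase of leukocytes of every kind is argued against as well, since the T cell (-0.27) and dendritic cell (-0.29) lists did not rise. The neutrophil list lay 1.64 above these lists, which had -0.28 jointly (exact permutation p = 0.016). It lay 1.34 above the 5 other leukocyte lists fixed in advance, which had a joint mean change of 0.02 (exact permutation p = 0.0079). The neutrophil list was picked for its rise in these arrays, so these p-values are not evidence by themselves. Among the 5, monocyte and macrophage markers (0.63) and B and plasma cell markers (0.28) were higher, so more myeloid cells in general are not excluded. More neutrophils and higher expression per cell both stay open as hypotheses, and no test here separates them.

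The third pattern is the rise of the muscle genes Ankrd2, Sln, Mybph, Csrp3 and Smpx (the last 3.14-fold, chosen after its value was seen). More muscle in the stretched samples as the whole cause is argued against: the muscle list changed by -0.02, and the change plus 2 standard errors was 0.76. This lies below the smallest change of the 5 genes (1.65). The 5 genes were picked for their rise, so 1.65 is a lenient yardstick, here and for slow-type fibres. The tests of regeneration or denervation and of load response used 0.82, derived from the same genes. Without stretch replicate 1, which lay at -1.35, the muscle list changed by 0.31 and passed, so some more muscle in the other stretched samples is not excluded. Slow-type fibres as the whole cause are argued against too, with a mean change of 0.28 (exact permutation p = 0.13) and an upper bound of 0.58. The slow-fibre mean was -0.15 in stretch replicate 1 and 0.34 to 0.45 in the other stretched arrays. The non-stretched arrays lay at -0.23 to 0.19, so some more slow fibres in the other stretched samples are not excluded. Muscle regeneration or denervation is argued against as well, with -0.12 (exact permutation p = 0.75) and an upper bound of 0.49. Some members of that list lay low, such as Chrng (2.92 with stretch) and Myod1 (3.31), and could show little change. A wider load response of muscle may fit but was not established: the 10 load-responsive genes, written down before their values were seen, were all positive. Among them were Mustn1 (log2 change 2.08) and Flnc (1.17), and the list had a mean change of 0.90 and an exact permutation p of 0.063. Its mean was -0.33 in stretch replicate 1, within the non-stretched range (-0.49 to 0.38), and 1.00 to 1.37 in the other stretched arrays. That array was also lowest in the muscle list.

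Over 100 splits of the 9 arrays into 5 and 4, the real one included, 3 called at least as many genes as the real split (48). Likewise 3 called at least as many lists (23). Both shares lie under the 5% set beforehand. Only 100 of the 126 possible splits were run and testing both counts was not corrected for, so a chance division of the arrays is not excluded. The median of the other splits was 0 genes but 10 lists, so a camera call by itself is weak evidence here. The highest other split, with 140 genes and 24 lists, moved stretch replicate 3 to the non-stretched arrays, and the split that exchanged stretch replicate 3 and no-stretch replicate 4 called 76 genes and 21 lists, which points to a structure of the samples beside the groups. These 2 arrays were close in neutrophil chemokines (1.22 and 1.15 above the non-stretched mean), but their hair follicle stem cell means (-0.72 and -0.21) and melanocyte means (-0.91 and 0.10) lay on the sides their labels give, whereas their sebaceous means (-0.49 and -0.72) did not. Stretch replicate 3 had the strongest change of the 5 stretched arrays in activated keratinocyte (1.72), type II interferon (1.11), melanocyte (-0.91) and fibroblast genes (-0.85), which argues against a response weak in every list, but the weakest in 10 of the 23 called lists, more than any other stretched array: neutrophil chemokines (1.22), neutrophil markers (0.70), IL-6 (0.45), TNF (0.36), matrix proteases (0.33), monocyte (-0.01), cell cycle (-0.16), dendritic cell (-0.12), hair shaft (-0.31) and sebaceous genes (-0.49), the monocyte and cell cycle values with the sign opposite to the group's. For adventitial-type fibroblast genes it lay at -0.77, with the other stretched arrays (-1.28 to -0.71) and below the non-stretched ones (-0.20 to 0.16). A wrong label of this array was not tested by itself and stays open, as does a weaker response in part of the lists.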

How the results depend on the processing

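The omission of the 2 arrays of lowest weight was chosen after seeing the data, and the other alternatives were set before. The direction of the 48 genes held wherever they were tested, but the number of genes past the threshold did not. Leaving out arrays could not turn the direction, since the groups do not overlap for these genes. It was 105 without the lowest 25% of genes by mean level, 103 without the lower 50%, 157 with array weights, 15 without the 2 arrays, 211 at an adjusted p of 0.1 and 556 at an unadjusted p of 0.05 with a 2-fold change, and from 2 to 195 when 1 array was left out. Fewer genes tested may be part of the gain with the filters, but no cause of it was tested. The list count was 0 with an estimated correlation, 13 with fry, 0 with an exact permutation of list means (smallest adjusted p = 0.0635), and between 21 and 24 in the other settings.

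Il1b passed the threshold without the lowest 25% (3.71, adjusted p = 0.0497), without the lower 50% (3.71) and with array weights (3.72), and Il6 without the lower 50% (4.19). When 1 array was left out, Il1b ranged from 3.26 to 4.22 and Il6 from 3.60 to 4.86. With the replicate number as a replicate block, 221 genes passed, Il1b changed by 3.71 and Il6 by 4.52 (adjusted p = 0.00337 and 0.0151). Stretch replicate 5 has no same-numbered partner, so the block fit takes the change from the other arrays. Without that array and without the block, 13 genes passed and Il1b had limma adjusted p = 0.119. Same-numbered samples correlated at -0.06, -0.02, 0.06 and 0.34, and not every sample correlated best with its own number. These few correlations do not settle whether the numbers pair the samples.

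Values that turned sign were all of results that had not passed. Il23a was 0.0145 after quantile normalization, 0.0268 after median centring, 0.104 with array weights, 0.196 without the 2 arrays, and -0.14 to 0.178 when 1 array was left out. The mean log2 change of the list IL-23/IL-17 axis was 0.0251, 0.0666, 0.0187 and 0.0526 in the same order, 0.0525 without the lowest 25%, 0.181 without the lower 50%, and -0.0486 to 0.0456 with 1 array left out. The mean log2 change of the list skeletal muscle markers was 0.0472 after median centring, 0.0773 with weights, 0.277 without the 2 arrays, and -0.223 to 0.312 with 1 left out. The type I interferon list was -0.263 with weights, -0.291 without the 2 arrays, and -0.414 to 0.515 with 1 left out, and the antimicrobial list -0.0253 to 0.465. The cause was not tested. Of the named genes' values, 1669 kept direction and side of the threshold, 114 gained a call, 161 lost one and 6 turned. Signal over background was not assessed, so low genes such as Il23a are limited most.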

Other observations

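The lists used here were chosen after the called genes had been seen, and written down before the values of their members were looked at. A group of fibroblast genes outside the fixed lists was lower together with stretch. All 13 measured genes typical of adventitial-type fibroblasts, the CD34-positive fibroblasts around vessels and in deep dermis, had negative changes, with a mean of -0.97 (SE 0.13). Sfrp4, a secreted Wnt modulator, changed by -2.32, Pcolce2 by -1.25, Efemp1 (12.36 with stretch, 13.61 without) by -1.25, Cd248 by -1.23 and Pi16 by -0.67, all on the log2 scale. None passed limma's threshold over all genes (adjusted p = 0.081 for Sfrp4 and 0.053 for Cd248), while the list mean was lower in all 5 stretched samples with an exact permutation p of 0.0079 (two-sided, the smallest possible). The fall of Cd34, Dpt, Tnxb and Islr is therefore consistent with a lower level of this fibroblast program (mean change -0.97), as a hypothesis; fewer such cells and a changed state of them are not separated.

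The Ccl21 chemokine genes fell, Ccl21a by 1.35 on the log2 scale (2.54-fold). Of 7 other lymphatic genes, 3 were higher and 4 lower, with a mean change of 0.11 (exact permutation p = 0.48) and a lower bound of -0.20. Pdpn (log2 change 0.73) and Itga9 (0.61) raised this mean, whereas Lyve1 (-0.10), Prox1 (-0.30), Flt4 (-0.04) and Mmrn1 (-0.29) were lower. None of these 4 fell as far as Ccl21a. Prox1 and Mmrn1 lay low, at 4.59 and 4.99 with stretch, where falls are understated, and Lyve1 had a standard error of 0.47. These genes therefore do not decide whether a lower share of lymphatic vessels was the whole cause. A loss of these vessels is not excluded. A change of Ccl21 expression within the vessels stays open and was not tested.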
